A study of Zea mays with 9 samples.

How the data were processed

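The series holds 9 chromatin immunoprecipitation libraries (ChIP-seq) from leaf protoplasts of the maize inbred line B73, in 3 groups of 3. Per the labels' protocols, protoplasts carried a GFP fusion of ZmbZIP60, a GFP fusion of ZmbZIP17, or the GFP vector alone, and sheared chromatin was pulled down with a GFP antibody. The titles name the second factor ZmbZIP17 and another label field names the same samples bZIP91. The title is followed here. The letter C that ends both factor names in the titles is not explained there. The labels state for all 9 samples that seedlings received tunicamycin at 5 mg per ml in DMSO, so no untreated arm was compared. Sequencing ran for 150 cycles.

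Per the submitters' processing notes, Trimmomatic 0.36, BWA, MACS2 and bedtools were used. The aligner settings are not given in the sources used here. Per the file headers, the libraries of each group were merged and peaks were called with MACS2 (version 2.1.0.20150420) on each merged pull-down against the merged vector control. The call used no fragment model, tags extended to 200 bp, a q cutoff of 0.05, an effective genome size of 2.7 Gb, 1 tag kept per position and strand, and the larger dataset scaled down to the smaller. The merged input of the ZmbZIP60 call carries the numbers 1 and 3 in its name, and the other merged inputs carry 1, 2 and 3. Whether replicate 2 of ZmbZIP60 was left out is not stated. The 2 peak lists are therefore pooled, no value per replicate was used here, and no spread between replicates can be given for any value. Contig names in the lists carry the mark of version 4 of the B73 assembly. Coordinates are 1-based and follow that assembly.

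Each list was deposited as 3 files that agree in interval, summit, fold, p and q for all 3042 ZmbZIP60 and all 282 ZmbZIP17 peaks. Per the file headers, the fold enrichment is a ratio of pull-down to local control at the summit, and the pileup is the signal of extended tags covering the summit. The authors' −log10 p and −log10 q come from the Poisson test of MACS2. The deposited score column is 10 times the −log10 q and was not used further. All values per peak are the authors' own, and tests of fold were made within a list. Folds of shared regions are given from both lists, which were scaled separately, and folds of one list were set against the fold that the other call needed.

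The control level behind each peak was recovered from the deposited fold, which equals (pileup + 1)/(control + 1). Divided by the depth scaling, this gave a control background in unscaled tags over 200 bp that was whole within 0.02 for 78.5% of ZmbZIP60 and 82.3% of ZmbZIP17 peaks. The rest are means over wider windows, and the lowest ZmbZIP60 value, 3.50, equals the mean over the genome. Control tags below mean this recovered background, which is not always a count at the summit. Recomputing the Poisson −log10 p from pileup and control gave values within 0.5 of the deposited ones for 100% of peaks in both lists. Peaks were split at 20 control tags over 200 bp into low and high background. The mean over the genome is 3.50 control tags. Peaks less than 10000 bp apart were joined into loci. The split and the locus distance were chosen after seeing the data.

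After removal of tags at used positions, the headers give 18726110 tags for ZmbZIP60, 126318506 for ZmbZIP17 and 47193255 for the control. The removed share was 26%, 41% and 9%. Because 1 tag is kept per position and strand, no unscaled pileup can exceed 400 tags. The ZmbZIP17 pull-down was scaled down to the control, so its pileup cannot exceed 149 on the deposited scale. For each peak of one list, the fold that the other call needed at that background was computed from the Poisson test and the lowest −log10 p listed (5.39 for ZmbZIP17 and 4.24 for ZmbZIP60).

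Overlap means at least 1 bp shared and was computed on the 10 chromosomes and checked with bedtools 2.31.1. It was tested by a one-sided permutation test with 1000 random placements of the ZmbZIP17 peaks on their own chromosomes, up to the last position listed. Shares of peaks were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 6 comparisons of the lists. These comparisons were chosen after seeing the data. Fold differences were tested by two-sided permutation tests of the difference of medians with 100000 resamples, with intervals from 2000 bootstrap resamples. Intervals of shares are exact Clopper-Pearson at 95%. Tests take peaks or loci as units. They describe these merged libraries, and they do not measure biological replication. Intervals cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap test was tested on simulated data. With no effect, 1 of 50 random lists of 282 peaks had a p at or under 0.05, and after planting 50 peaks it found 51 overlaps. The median test gave a p at or under 0.05 in 3 of 50 random splits. These lists and splits were drawn by the same random scheme as the tests, without the clustering or the background of the real peaks. They check the code and cannot show that the tests hold for clustered peaks at high background.

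The overlap test, the fold test, their alternatives and the rule for named items were fixed before the data were examined. Alternatives were a −log10 q of at least 5, a fold of at least the list's median, chromosomes alone, 50% reciprocal overlap, summits within 100 bp and equally long lists, and further ones by background and by locus were added after seeing the data. The rule names the 10 peaks per list with the highest −log10 q on the chromosomes and the 10 shared regions with the highest lower −log10 q. The 5 peaks with the highest fold per list were added after the values were seen. The rule also asked for genes near these peaks and for genes of the unfolded protein response with a promoter peak. Neither is reported, because the only gene table used here belongs to a later assembly and coordinates were not moved between assemblies. For the same reason 5 planned tests were not run: promoter share, bZIP motif at summits, all 6-mers, gene lists, and fold with and without the ACGT core. All columns of the 6 files were mapped to the group or comparison they name.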

Results

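The genomic regions occupied by 2 maize transcription factors of the bZIP family were mapped in leaf protoplasts of the inbred line B73. In plants, bZIP60 is the factor whose mRNA is spliced by the endoplasmic reticulum (ER) stress sensor IRE1, and bZIP17 is a membrane-anchored factor released by proteolysis under ER stress. Each was expressed as a GFP fusion in 3 libraries and pulled down with a GFP antibody, and 3 libraries with the GFP vector alone were the control. Tunicamycin, named in the labels of all samples, blocks N-glycosylation and causes ER stress. Merged by group, the depth after filtering was 18726110 tags for ZmbZIP60, 126318506 for ZmbZIP17 and 47193255 for the vector control. One peak list was called per factor on the merged libraries, so no value below has a replicate error.

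One comparison asks where ZmbZIP60 was enriched over the vector control. The ZmbZIP60 list held 3042 peaks in 1885 loci, of which 2489 peaks lay on the 10 chromosomes and 553 on 78 unplaced contigs. The peaks are described by their control background, because the call lists lower folds as the background rises and the fold at high background is limited by the 1 tag kept per position. The lowest listed fold on the chromosomes was 2.59 at low and 1.54 at high background, so the folds of these classes do not compare their enrichment. On the chromosomes, 1274 peaks had under 20 control tags over 200 bp. Their median fold enrichment was 4.90, with an interquartile range of 4.19 to 5.997, and their median length was 275.5 bp. They lay mostly apart from each other, and 1109 of the 1188 loci that held such peaks held a single low-background one. Some of the 1188 loci also held high-background peaks. The other 1215 chromosomal peaks had a median background of 86.0 control tags, against a genome mean of 3.50, and a median fold of 2.80 with an interquartile range of 2.37 to 3.20. The contig peaks resembled this second class, with a median background of 184 control tags and a median fold of 2.24.

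The strongest ZmbZIP60 peaks by fold had little control signal and lay on 5 different chromosomes. The highest fold, 15.4, was at chromosome 5, 71289500 to 71290025, where 51 pull-down tags (95% Poisson interval 38.0 to 67.1) stood over 6 control tags. It was followed by chromosome 6, 161701542 to 161702035, with a fold of 13.7 and 40 tags over 5 control tags. A fold of 13.2 was listed at chromosome 1, 197077441 to 197077794, one of 13.1 at chromosome 7, 5053311 to 5053619, and one of 13.05 at chromosome 9, 137027810 to 137028339. None of these 5 regions, which were chosen after their values were seen, was in the ZmbZIP17 list. Ranked by significance instead, the list was led by high-background regions. The highest −log10 q, 87.1, was at chromosome 2, 220735787 to 220736714, where the pileup reached 400 tags, the highest value that the calling allows, over 292 control tags. The 10 most significant chromosomal peaks had 137 to 292 control tags and folds of 3.07 to 4.10. A pair of them lay close together on chromosome 10, at 48839432 to 48840010 with a fold of 3.59 and at 48842276 to 48844868 with a fold of 3.18. Further peaks of this group were at chromosome 2, 66781385 to 66784206 (fold 3.49), chromosome 1, 15412725 to 15413511 (fold 3.11), chromosome 9, 90541082 to 90544587 (fold 3.07), and chromosome 3, 75411552 to 75412637 (fold 4.10). The remaining ones were at chromosome 3, 95743017 to 95743598 (fold 3.38), chromosome 2, 206605668 to 206607568 (fold 3.30), and chromosome 10, 100534637 to 100535428 (fold 3.22). At all 10 summits the ZmbZIP17 call needed a pileup above the highest possible value, so that no ZmbZIP17 peak at these summits is listed carries no information. The genes at these positions were not analysed here.

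**Figure D1:**
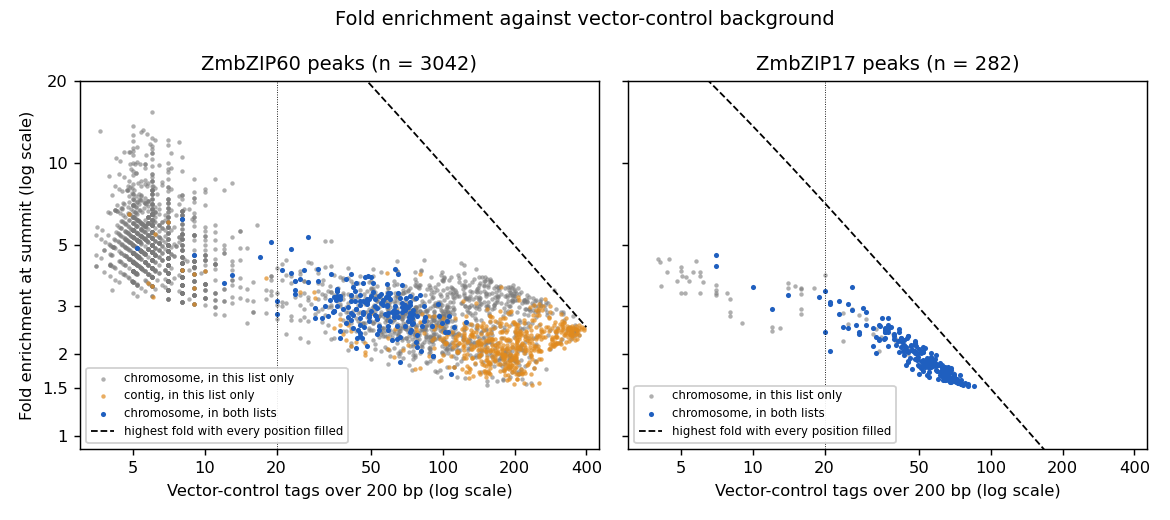
Fold enrichment at each peak summit (log axis) against the vector-control tags over 200 bp (log axis), for ZmbZIP60 (left) and ZmbZIP17 (right). Points are peaks coloured by place and by presence in both lists, the dotted line marks 20 control tags, the dashed line is the highest fold possible when every position holds 1 tag per strand, and ZmbZIP60 folds reach 15.4 where ZmbZIP17 folds reach 4.61.

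The next comparison asks where ZmbZIP17 was enriched over the same control. The ZmbZIP17 list held 282 peaks in 105 loci, all on chromosomes, from the deepest merged library. Of these, 236 lay at high background, with a median of 52.0 control tags and a median fold of 1.90. The other 46 lay at low background, with a median fold of 3.50 and an interquartile range of 3.30 to 3.88. The highest fold in the list was 4.61, at chromosome 1, 163878602 to 163878884. Of the 105 loci, 66 held a single peak, and the 5 loci with most peaks held 102 peaks, or 36.2% of the list. These 5 loci were chromosome 2, 79934090 to 79977161, with 23 peaks, chromosome 4, 160279382 to 160316742, with 23, chromosome 4, 115311046 to 115350237, with 22, chromosome 9, 6516464 to 6554870, with 20, and chromosome 4, 115256189 to 115287183, with 14. Their median folds ranged from 1.65 on chromosome 9 to 2.70 in the last of the chromosome 4 loci. Chromosome 4 alone held 72 of the 282 peaks, or 25.5%, in 13 loci. In the ZmbZIP60 list it held 265 peaks, or 10.6% of those on chromosomes. By locus the shares were closer, at 13 of 105 for ZmbZIP17 and 165 of 1749 for ZmbZIP60. The contrast in peaks therefore comes largely from the chromosome 4 clusters named above.

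The most significant ZmbZIP17 peaks came largely from the neighbouring chromosome 4 clusters. The highest −log10 q, 15.2, was listed both for chromosome 4, 115280744 to 115281046, with a fold of 3.91, and for chromosome 1, 235237244 to 235237579, with a fold of 3.51. Of the 10 most significant peaks, 6 lay in the pair of chromosome 4 loci that start at 115256189 and 115311046. Besides the first, these were the peaks at 115319264 to 115319779 (fold 3.41), 115258653 to 115258909 (fold 2.96), 115319999 to 115320219 (fold 3.49), 115326447 to 115326963 (fold 2.85) and 115284505 to 115284985 (fold 3.14). The others were chromosome 4, 239409741 to 239410262 (fold 2.71), chromosome 2, 209804481 to 209804868 (fold 3.04), and chromosome 2, 79961737 to 79962248 (fold 2.71). Of these 10 peaks, 8 overlapped a ZmbZIP60 peak. The high-background ZmbZIP17 peaks filled a median of 68.0% of the available tag positions in the pull-down, which bounds their fold from above.

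**Figure D2:**
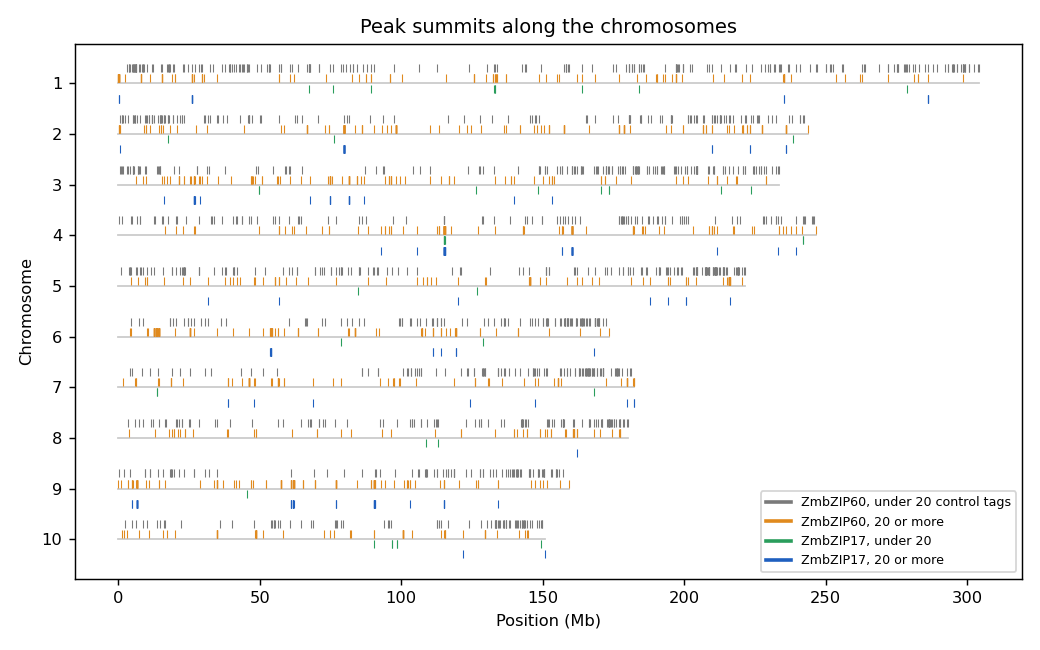
Position in Mb (horizontal axis) of each peak summit on the 10 chromosomes (vertical axis), with ticks for each chromosome from top to bottom for ZmbZIP60 peaks under 20 control tags, ZmbZIP60 peaks at 20 or more, ZmbZIP17 peaks under 20 and ZmbZIP17 peaks at 20 or more. The 1274 low-background ZmbZIP60 peaks lie on all 10 chromosomes, as do the 282 ZmbZIP17 peaks, of whose 105 loci 66 hold a single peak.

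A further comparison asks whether both factors occupied the same regions. Most ZmbZIP17 peaks lay on ZmbZIP60 peaks: 221 of 282 overlapped one (78.4%, 95% interval 73.1 to 83.0), against a mean of 0.356 in random placements. No placement exceeded 3 (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). The placements were not matched for background, whereas 236 of the 282 ZmbZIP17 peaks lay at high background. Lists that both favour high-background regions could pass this test without the factors sharing sites. It therefore cannot decide whether both factors occupied the same regions. Counted as loci, 71 of 105 overlapped (67.6%, 95% interval 57.8 to 76.4). From the other side, 187 of the 3042 ZmbZIP60 peaks overlapped a ZmbZIP17 peak (6.15%, 95% interval 5.32 to 7.06). Both calls used the same control libraries, so part of the overlap may be common to the control, and this could not be separated from peak lists.

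The overlap lay mostly in high-background regions. At high background 215 of 236 ZmbZIP17 peaks overlapped a ZmbZIP60 peak (91.1%), and at low background 6 of 46 did (13.04%), against a mean of 0.015 in random placements of low-background peaks (one-sided permutation test, p = 0.001). Counted as loci, the shares were 66 of 72 (91.7%) and 5 of 33 (15.2%), which differed by Fisher's exact test (two-sided p = 8.74e-15, adjusted p = 1.31e-14 over 6 comparisons). Of the 1274 low-background ZmbZIP60 peaks on chromosomes, 7 overlapped a ZmbZIP17 peak (0.549%, 95% interval 0.221 to 1.13). Of the 1215 high-background ones, 180 did (14.8%, 95% interval 12.9 to 16.9). At high background the calls were not equally able to list a region. The ZmbZIP17 pileup needed at the summit exceeded its highest possible value of 149 at 482 of 1215 chromosomal ZmbZIP60 peaks (39.7%). It did so at 486 of all 553 contig peaks (87.9%), of which 541 lay at high background. Of the peaks above this ceiling, 7 chromosomal ones met a ZmbZIP17 peak. Absence from the ZmbZIP17 list carries no information on binding at those summits. Of the 733 high-background chromosomal ZmbZIP60 peaks under the ceiling, 173 met a ZmbZIP17 peak (23.6%, 95% interval 20.6 to 26.8). Most of the high-background ZmbZIP60 peaks that the ZmbZIP17 call could list were therefore in the ZmbZIP60 list alone.

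**Figure D3:**
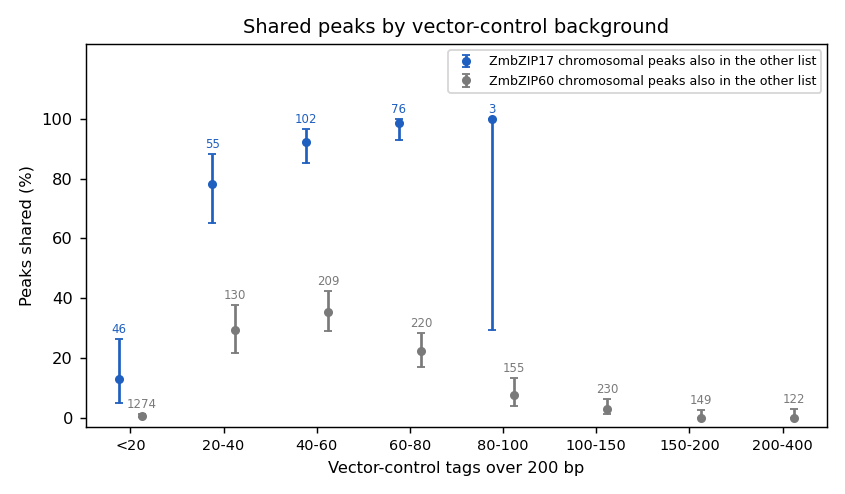
Percentage of chromosomal peaks of each list that overlap a peak of the other list (vertical axis), by vector-control tags over 200 bp (horizontal axis), with bars for exact 95% binomial intervals and the number of peaks in each bin. The ZmbZIP17 share rises from 13.04% under 20 control tags to 98.7% at 60 to 80.

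The regions shared with the highest significance in both lists lay on chromosomes 1, 2, 4, 5 and 6, with 5 of the 10 on chromosome 4. Their summits were at most 33 bp apart, except for 454 bp at chromosome 2, 79962019. The first was at chromosome 1, where the ZmbZIP60 peak at 235237248 to 235237578 had a fold of 5.38 and the ZmbZIP17 peak a fold of 3.51, with summits 5 bp apart. On chromosome 4, the ZmbZIP60 peak at 115319231 to 115319794 had a fold of 5.15 in its list and the ZmbZIP17 peak 3.41 in its own, with summits 12 bp apart. The ZmbZIP60 peak at 115284527 to 115285011 had a fold of 4.84 and the ZmbZIP17 peak 3.14, with summits 1 bp apart. Also on chromosome 4, the peaks at 115258625, 115311028 and 239410061 (ZmbZIP60 starts) had ZmbZIP60 folds of 4.11, 3.30 and 3.19 and ZmbZIP17 folds of 2.96, 2.47 and 2.71. The other 4 of the 10 were at chromosome 2, 209804490 (folds 3.67 and 3.04), chromosome 2, 79962019 (2.79 and 2.71), chromosome 5, 200547721 (4.07 and 3.10), and chromosome 6, 78664746 (4.52 and 3.24). Over all 229 overlapping pairs the median distance between summits was 108 bp. The lists were scaled separately, so folds of a region in both lists do not compare occupancy between the factors.

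Within each list, shared peaks had a lower fold than unshared ones when all backgrounds were pooled. The tests and intervals of fold took single peaks as units, although neighbouring peaks of the same locus are not independent. A single chromosome 4 locus held 19 of the 187 shared ZmbZIP60 peaks and 22 of the 221 shared ZmbZIP17 peaks. The p-values may therefore be too small and the intervals too narrow, and no test of fold by locus was run. For ZmbZIP60 the medians were 2.96 for 187 shared and 3.31 for 2855 unshared peaks (difference -0.353, bootstrap interval -0.488 to -0.253, permutation p = 0.0189, adjusted p over 2 tests 0.0189). The unshared peaks include all 553 contig peaks, with a median fold of 2.24. They also include all but 7 of the 968 peaks above the ZmbZIP17 ceiling, contig peaks among them, where being unshared carries no information. At high background on the chromosomes the order turned, with 2.92 for 180 shared and 2.77 for 1035 unshared peaks (difference 0.147, interval 0.0421 to 0.262, permutation p = 0.0161), but the shared peaks there had the lower background, with a median of 52.8 against 97.0 control tags. At low background the 7 shared peaks did not differ detectably from the 1267 unshared ones (difference -0.306, interval -1.13 to 0.319, permutation p = 0.604). There the shared peaks had the higher background, with a median of 12 against 6 control tags. For ZmbZIP17 the medians were 1.88 for 221 shared and 3.31 for 61 unshared peaks (difference -1.43, interval -1.59 to -0.903, permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted 2e-05). At high background the difference was -0.403 (interval -0.621 to -0.208, permutation p = 0.00117) with the higher background in shared peaks, a median of 53.0 against 34.6 control tags. At low background it was -0.0859 with 6 shared peaks (interval -0.446 to 0.863, permutation p = 0.696). Those 6 also had the higher background, a median of 11 against 7 control tags. At 20 to 40 control tags, where backgrounds were closer, neither difference passed the test, with -0.0100 for ZmbZIP60 (permutation p = 0.936) and -0.0345 for ZmbZIP17 with 12 unshared peaks (permutation p = 0.715). Where the summits had to lie within 100 bp, the ZmbZIP17 difference was 0.0420 and did not pass the test (permutation p = 0.454), and the ZmbZIP60 difference was -0.277 (permutation p = 0.119). Of the 61 ZmbZIP17 peaks outside the ZmbZIP60 list, 40 were at low background. A fold that the ZmbZIP60 call could list at that background was found at 48 of the 61, and 13 had a fold under its limit. With lists scaled separately, this does not show which of them the ZmbZIP60 call would have listed.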

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

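The comparisons of shares between the lists and the tests of saturation, of repeated DNA and of the ceiling on the contig peaks were chosen after the result was seen. So were the test of the peaks clear of the detection limit and that of contig loci within bins of background. Those of all low-background peaks against the detection limit and of the contig loci under the ceiling were written before, the latter with the 0 on contigs known but not the number of such loci or the chromosomal share.

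The lists differed in the kind of region they held. Among loci on chromosomes, 67.1% of the ZmbZIP60 loci and 31.4% of the ZmbZIP17 loci had a median background under 20 control tags (Fisher's exact test over loci, p = 8.5e-13, adjusted p = 1.02e-12 over 6 comparisons). Whether the detection limit of the ZmbZIP17 call contributes for all 1274 low-background ZmbZIP60 peaks cannot be told: 100% had the fold that this call needed, but the ZmbZIP60 call needed as high a fold at each of them, so selection fixed that share. For the 661 whose lower counting limit of the fold was above the fold needed, 5 (0.756%, 95% interval 0.246 to 1.76) were in the ZmbZIP17 list, which decides nothing because it takes both pull-downs to enrich equally, and folds of separately scaled lists cannot show that. The detection limit together with weaker pull-down in the ZmbZIP17 libraries stays open, as does a difference between the factors.

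Contigs held 18.2% of the ZmbZIP60 peaks and 0 of the 282 ZmbZIP17 peaks (Fisher's exact test over loci, 136 of 1885 against 0 of 105, p = 0.000998, adjusted p = 0.000998). The ceiling on the scaled ZmbZIP17 pileup is a candidate explanation for 87.9% of the contig peaks, at whose summits the pileup needed exceeded it, although 7 of 482 chromosomal peaks of that kind met a ZmbZIP17 peak. By definition the ceiling does not bar a listing at the high-background contig loci under it. Of these, 0 of 40 were in the ZmbZIP17 list against 57 of 410 chromosomal loci (13.9%, two-sided Fisher's exact test, p = 0.00524). The 0 was given by the pattern itself, so the test weighs only the number of such loci and the chromosomal share. With contig and chromosomal loci listed at one rate per bin of background, 3.95 listed contig loci would be expected (one-sided exact test, p = 0.0114), and the 12 low-background contig peaks were not tested. Loci were matched on background alone and not on fold. Contig peaks under the ceiling, low-background ones included, had a median ZmbZIP60 fold of 2.48, against 2.84 for high-background chromosomal ones. Among all ZmbZIP60 peaks at 20 to 60 control tags, the contig and chromosomal medians were 2.46 and 3.03. At 60 to 100 they were 2.37 and 2.70, so contig folds were lower at like background. Whether this lowered their listing was not tested. A difference between the merged libraries in DNA from unplaced sequence, or between the factors, stays open for these 40 loci and was not tested.

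The ZmbZIP60 peaks at high background had a median ratio of unscaled pull-down to control tags of 1.02, against 2.6 at low background, and filling of every position in both libraries would give a fold of 2.51 by scaling alone. On the chromosomes the ratio was 1.15 (bootstrap interval 1.13 to 1.16, 1093 peaks) under 200 control tags, above the 1 that filled positions allow. The ratio alone cannot decide, because these summits are pull-down maxima that passed the call. A median of 21.25% of positions was filled at these peaks, which argues against saturation as the whole cause there. At 200 to 400 the ratio was 1.04 (0.983 to 1.13, 122 peaks), with a median fold of 2.60 and 66.9% of positions filled. Saturation cannot be told apart from enrichment at those 122 peaks. Ratios at summits are raised by an amount not measured, since a summit is the highest point of the pull-down. Contig summits under 200 control tags had a ratio of 0.863 (0.840 to 0.880, 307 peaks). Of them 0.977%, against 19.6% on chromosomes, exceeded the control by over 2 SD. These pooled values are not matched for background, since 257 of the 307 contig peaks but 379 of the 1093 chromosomal ones lay at 100 to 200. At 20 to 60 the ratio was 1.01 (0.915 to 1.11) on contigs and 1.25 (1.23 to 1.28) on chromosomes. At 60 to 100 it was 0.956 (0.872 to 1.01) and 1.09 (1.07 to 1.12), and at 100 to 200 it was 0.842 and 1.097. Contig folds had a median of 2.46 at 20 to 60 control tags (20 peaks), 2.11 at 100 to 200 and 2.44 (SD 0.128, 70 peaks) at 300 to 400, and the last value is consistent with saturation at 1 tag per position for those 70 peaks. More repeated or organelle-like DNA in the pull-down cannot be told apart from enrichment, because no sequence was used and the coefficient of variation of the fold, 22.1% against 32.2% at low background, does not decide.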

How the results depend on the processing

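No paired analysis was possible because the replicates were merged before peak calling, and for the same reason no replicate could be left out. The alternatives by background class, by locus and by moving peaks together, and all those of the low-background counts, were chosen after seeing the data. Of 33 values under alternatives, 14 kept their direction and side of the threshold or stayed within 1.5 times the count. With fold at or above the list's median, 1522 ZmbZIP60 and 141 ZmbZIP17 peaks remained, by construction. Counted as loci there were 1885 and 105, and at low background alone 1286 and 46. A −log10 q of at least 5 left 104 ZmbZIP17 peaks and 2290 ZmbZIP60 peaks. Of the low-background chromosomal peaks, that threshold left 710 of 1274 for ZmbZIP60 and 15 of 46 for ZmbZIP17, and a split at 10 control tags left 30 for ZmbZIP17. The overlap stayed above random placement, which was not matched for background, under 7 of 8 alternatives. Of all 282 ZmbZIP17 peaks it held 40.8% with 50% reciprocal overlap and 40.1% with summits within 100 bp. It held 66.3% of the 104 peaks with a −log10 q of at least 5 and 67.6% of the 105 loci. By background in both lists it held 13.04% of 46 low and 90.7% of 236 high-background peaks. It fell to 0% (permutation p = 1) when the ZmbZIP60 list was reduced to its 282 most significant peaks, 267 of which had a summit where the pileup needed in the ZmbZIP17 call exceeded its ceiling. The fold difference between shared and unshared ZmbZIP60 peaks no longer passed the test with summits within 100 bp (-0.277) and at low background (-0.306, 7 shared peaks). It reversed at high background (0.147) and at 20 to 100 control tags (0.160), with single peaks and not loci as units. The ZmbZIP17 difference no longer passed at low background (-0.0859, 6 shared peaks). With summits within 100 bp it was 0.0420 (interval -0.127 to 0.236, permutation p = 0.454), which shows no difference in either direction. That setting counts 169 peaks as unshared, among them overlapping peaks with more distant summits. At 20 to 40 control tags neither passed, with -0.0100 for ZmbZIP60 and -0.0345 for ZmbZIP17. The cause was not tested. Placement matched for distance to genes was not run, because it needs an annotation of the same assembly. The low-background ZmbZIP60 peaks rest on a median pileup of 16 tags, which limits the precision of their folds.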

Other observations

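The test of position along the chromosomes was written before its result was seen, and the split by background and the blocks of peaks were chosen after seeing the data.

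Low-background ZmbZIP60 peaks lay towards the chromosome ends. Of 1188 loci that held such peaks, 824 (69.4%, 95% interval 66.7 to 72.0) fell in the outer 50% of their chromosome. This outer part was taken evenly from both ends and measured up to the last listed position. High-background ZmbZIP60 loci fell in it in 302 of 576 cases (52.4%, 95% interval 48.3 to 56.6). Some loci held peaks of both classes and count in both. The classes differed (Fisher's exact test, odds ratio 2.05, p = 7.69e-12), and the low-background share was the higher on 9 of 10 chromosomes, chromosome 8 being the exception with 68.4% against 74.4%. Low-background ZmbZIP17 loci showed no such excess, with 12 of 35 in that outer part (34.3%, 95% interval 19.1 to 52.2; two-sided exact binomial test, p = 0.0895). As a hypothesis, the low-background ZmbZIP60 class may follow the gene-rich outer parts of maize chromosomes. The odds ratio bears on position alone, and neither distance to genes nor mappability along the chromosomes was tested.

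The shared loci with most ZmbZIP60 peaks were extended blocks, which follows from picking them by their number of joined peaks. Of the 105 ZmbZIP17 loci, 66 held a single peak. The chromosome 2 block at 79917643 to 79977058 held 30 ZmbZIP60 peaks over 59416 bp and met 23 ZmbZIP17 peaks. The chromosome 4 block at 160247893 to 160316696 held 30 ZmbZIP60 peaks and met 26 ZmbZIP17 peaks. The chromosome 9 block at 6513926 to 6556182 held 19 and met 20. The ZmbZIP60 peaks of these blocks had median backgrounds of 65.3, 58.5 and 68 control tags, in that order, against a genome mean of 3.50. Without the 5 loci richest in ZmbZIP17 peaks, 135 of the remaining 180 ZmbZIP17 peaks still overlapped a ZmbZIP60 peak (75%, 95% interval 68.0 to 81.1). Not every dense block was shared: at chromosome 2, 98024768 to 98053181, 18 ZmbZIP60 peaks had a median background of 64.0 control tags and met no ZmbZIP17 peak.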
